A study of Homo sapiens with 9 samples.

How the data were processed

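RNA sequencing had been done on 9 samples of MCF7L, a line of the MCF-7 human breast cancer cell that expresses the estrogen receptor, in a subline that grows in the presence of tamoxifen. Per the labels' protocols the cells were kept in 100 nM 4-hydroxytamoxifen, the active metabolite of the drug, and transfected in suspension with siRNA in a cationic lipid reagent 3 days before harvest. The 3 groups were a non-silencing control siRNA and 2 siRNAs of different sequence against HIF-2alpha, the hypoxia-inducible factor subunit encoded by EPAS1, with 3 samples in each group. The labels do not say whether the samples of a group were separate cultures, so the p-values measure the spread between these samples, which may be technical.

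The deposited data were 2 tables, 1 for each HIF-2alpha siRNA against the control. Per the submitters' processing notes the tools were Bowtie2 2.3.4.1, Cufflinks 2.2.1 and Cuffdiff, with the human genome build hg38; their roles, order and settings are not given in the sources used here. Per the file headers each row is a gene locus with 1 FPKM (fragments scaled to transcript length and to the fragments mapped per library) value for each group, so the authors deposited FPKM pooled over the samples of a group and no value per sample. The deposited tables also hold a log2 fold change, a test score and a p-value and q-value from the authors' comparison for each row. No standard deviation or n can therefore be attached to a level printed here. The smallest p-value in both tables is 5e-05, shared by 2579 rows of the first table and 1853 rows of the second, and it gives q-values of 0.000264153 and 0.000360389. These are floors, so genes at them cannot be ranked by evidence.

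Both tables hold 56752 rows, which were joined on the locus identifier. The control FPKM values of the 2 tables differed in 2789 rows, by at most 0.01 FPKM or 0.205%, so the tables share their control libraries and their scaling. The deposited q-values were recomputed by Benjamini-Hochberg adjustment over the tested rows, with a largest difference of 5.2e-07. Log2 fold changes were recomputed from the FPKM values and differed from the deposited ones by at most 0.00031. Of the rows, 13625 were tested in the first table and 13356 in the second. The remaining rows were listed as not tested or, for 4 and 26 rows, as holding too much data. The 2 mitochondrially encoded protein genes that could be matched to a row, MT-ND6 and MT-CYB (the second shared with a transfer RNA gene), were listed at 0 and untested, and respiring cells use both, so a value of 0 in these tables can be a failed estimate and is reported only as listed at 0. A spreadsheet had turned 25 symbols of the second table into dates, so symbols were taken from the first. More than 1 symbol was listed in 2364 rows, where overlapping genes had been merged, and their single genes cannot be separated. Reads of near-identical gene copies can be shared between rows, which concerns the UGT2B family, histone genes, ribosomal protein genes, FTH1, PGAM1 and the pair ASNS and ASNSP1.

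Depth per sample is unknown. Low FPKM values of untested rows fall on steps, with a commonest log2 ratio of -0.224 in 67 of 6469 rows of the first table and -0.403 in 70 of 6591 rows of the second, but without gene lengths or values per library these steps did not give the depths. The authors' statistic was not on the scale of their p-value: its ratio to the normal quantile of the p-value had a median of 0.562 in each table. A standard error of the log2 fold change was therefore implied from the fold change over the statistic, multiplied by that ratio, and had a median of 0.17 over rows with FPKM of at least 1 with the first siRNA and 0.15 with the second. Standard errors without that factor were tried for the simulation of shared controls, as an alternative chosen after the data were seen.

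A gene is said to have risen, fallen or changed where the authors' q-value was below 0.05. This test had been planned as the main one for tables without values per sample. Genes tested in both tables were compared for direction. Because both comparisons use the same control libraries, 100 rounds of unchanged groups against shared controls were simulated from the implied standard errors, and the overlap of independent lists was computed as well. Fold changes used in correlations and gene lists were log2(FPKM + 0.1), which understates changes of low genes, over rows with FPKM of at least 1 in a group.

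Lists of genes were fixed before the data were examined, 31 in all. They covered the HIF system, hypoxia targets, HIF-2-preferred targets, glycolysis, estrogen-induced genes, luminal identity, basal markers, mesenchymal genes, secreted cytokines and proteases, MAPK response, G1/S replication, G2/M and mitosis, p53 targets, interferon-stimulated genes, NF-kB targets, the unfolded protein response, ATF4 targets and amino acid supply, cholesterol synthesis, fatty acid and lipid genes, nuclear-encoded oxidative phosphorylation, ribosomal proteins, adhesion and migration, TGF-beta and YAP targets, NRF2 targets, BCL-2 family and apoptosis genes, the small RNA pathway, mitochondrially encoded genes, immediate-early and heat shock genes, and markers of fibroblasts, endothelium and leukocytes. Some genes are in several lists, such as STC2, AREG and SERPINE1. For each list the median log2 fold change was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and it is said to stand apart below percentile 2.5 or above 97.5. This describes these libraries and is not a test over replicates. At least 5 expressed members were needed. The q-values were also adjusted over the list alone from the authors' p-values.

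The genes named in the text were chosen by a rule fixed before the data were examined: EPAS1, HIF1A, ARNT, FOXA1 and ESR1; for each siRNA the 10 highest and 10 lowest log2 fold changes among called single-gene rows with FPKM of at least 1 in the higher group and above 0 in both; the 12 shared rises and 12 shared falls with the highest smaller change; and up to 4 members per list, preferring those called in the same direction by both siRNAs, or 2 for lists that serve as checks. Names outside the rule are marked as chosen after their values were seen. Gene coordinates are those of GENCODE 29 on GRCh38, matched by symbol and place for 10545 of 12234 single-gene tested rows.

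A search of 3' untranslated regions used the longest annotated 3' UTR of 9091 coding genes tested in both tables with FPKM of at least 1 in a group. For each of 15486 words of 7 bases found in at least 100 of them, the mean log2 fold change, limited to 2 in either direction, of genes with the word was set against that of genes without it as a z value, after trends with UTR length, base composition and expression had been removed, and the bound was the most extreme z over all words in 100 permutations. On simulated data with a word planted at a shift of 0.3, the planted word ranked first in 5 of 5 trials. That shift is larger than the differences of medians found for the leading words, -0.15 with the first siRNA and -0.08 with the second. The trials therefore do not show that effects of such size would be found. For random lists of 20 genes drawn from the permuted fold changes of the first siRNA, 0 of 40 lists with no shift, 32 of 40 with a shift of 0.3 and 39 of 40 with a shift of 0.6 stood apart; for the second siRNA the counts were 4, 32 and 40 of 40. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots matplotlib 3.10.9. Alternatives covered the q threshold, a minimum FPKM, a minimum fold change, the pseudocount, centring on the median gene, 1 row per symbol and unmatched random lists.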

Results

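The data were group levels of gene expression from RNA sequencing of tamoxifen-resistant MCF7L breast cancer cells, with 3 control samples and 3 samples for each of 2 siRNAs against EPAS1, called siRNA 1 and siRNA 2 here. All cells were kept in 100 nM 4-hydroxytamoxifen and harvested 3 days after transfection. The tables gave 1 FPKM value per group, pooled by the authors, so no level below has a standard deviation, and the error of each comparison is carried by the q-value of the authors' deposited tables. FPKM of at least 1 was reached by 12086 rows in the control group, 12334 with siRNA 1 and 12045 with siRNA 2. The 10 highest rows held 12.2% of the summed FPKM in the control group and 10.3% with either siRNA. Depth per sample is unknown.

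The first question was whether each siRNA had lowered its target. EPAS1, which encodes the oxygen-regulated transcription factor subunit HIF-2alpha, fell from 85.2 FPKM with the control siRNA to 4.34 FPKM with siRNA 1 and to 6.90 FPKM with siRNA 2. That left 5.09% and 8.10% of the control level, log2 fold changes of -4.30 and -3.63. The q-values in the authors' deposited tables were the smallest each table holds, 0.000264 and 0.000360. EPAS1 lies on chromosome 2 from 46293667 to 46386703 on GRCh38 (XLOC_028121, ENSG00000116016.13). The 2 knockdown depths were not tested against each other. The related subunit HIF1A shares a row with the neighbouring SNAPC1 and a non-coding gene. That row stood at 194 FPKM in the control group, 227 with siRNA 1 and 157 with siRNA 2, and neither difference passed the threshold (q = 0.198 and q = 0.0635 in the authors' deposited tables). ARNT, the dimer partner of both HIF subunits on chromosome 1 from 150809705 to 150876768, had log2 fold changes of -0.24 and 0.03 with q-values of 0.0558 and 0.877 in the authors' deposited tables. Of the 7 tested genes of the HIF system, 1 rose and 2 fell with siRNA 1 and 1 fell with siRNA 2. EPAS1 itself is in this list: it was 1 of the 2 falls with siRNA 1 and the only change with siRNA 2. Adjusted over the list alone the counts were 4 and 1 changed genes. The list median did not stand apart from random lists with either siRNA (percentiles 56.7 and 60.7).

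The second question was what changed with siRNA 1. At q below 0.05 in the authors' deposited table, 5274 of 13625 tested rows changed, 3125 up and 2149 down, with a median change of 1.59-fold. At least 2-fold differences made up 711 of the rises and 582 of the falls over all tested rows, and 461 rises and 471 falls over the 9495 protein-coding single-gene rows. The lowest fold change among single-gene rows that passed the threshold and the level rule was that of MUC5AC, a secreted mucin, at -5.43. It was followed by CHAC1, which degrades glutathione and is induced under amino acid stress, from 30.4 to 0.782 FPKM (chromosome 15 from 40952962 to 40956519). WISP2, CLGN, the calcium-binding protein gene S100P, NUPR1, the glycerol channel gene AQP3, GALNT5 and the asparagine synthetase pseudogene ASNSP1 fell by 4.02 to 5.15 on the log2 scale. S100P went from 1706 to 65.7 FPKM. Reads of ASNSP1 may be shared with its parent gene, which was not tested. The highest fold changes among such rows were those of the non-coding RP11-369C8.1 (6.24), the protocadherin gene PCDH7 (5.77), the glucuronosyltransferase gene UGT2B11 (5.22), the transporter gene ABCC12 (5.17) and BRINP3 (4.86). RP11-90L1.8, CCDC129, CLCA2, LRRN1 and IYD followed, with log2 fold changes of 4.44, 4.27, 3.99, 3.98 and 3.81. The highest control level among these 10 genes was 0.594 FPKM, in UGT2B11.

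The same question for siRNA 2 gave 4067 changed rows of 13356, 2050 up and 2017 down, in the authors' deposited table, with a median change of 1.46-fold. Changes of at least 2-fold numbered 247 up and 399 down over all tested rows, and 172 up and 293 down over the 9415 protein-coding single-gene rows. Among changes of at least 1.5-fold falls outnumbered rises, 1047 to 793. FN1, which encodes fibronectin of the extracellular matrix, fell from 121 to 9.09 FPKM with siRNA 2 and to 46.4 FPKM with siRNA 1 (chromosome 2 from 215360440 to 215436172). MUC5AC (-4.19), GPR19 (-3.63), the nicotinic receptor gene CHRNA9 (-3.56), DNALI1 (-3.40), CD27-AS1 (-3.39), S100A2 (-3.36), ANXA1 (-3.22) and the inhibin subunit gene INHBE (-3.18) also fell. Without strand information CD27-AS1 cannot be separated from the sense gene. FAM3B (3.96), the protease gene TLL1 (3.82), the metalloprotease inhibitor gene TIMP3 (3.81), UGT2B11 (3.80), ABCC12 (3.31), the neuropeptide Y receptor gene NPY1R (3.26), the ketogenic enzyme gene HMGCS2 (3.24), RP11-369C8.1 (3.08), MGP (3.07) and the nuclear receptor gene NR5A2 (3.00) rose. Apart from MGP, the highest control level among these rises was 0.594 FPKM, in UGT2B11. TIMP3 was untested with siRNA 1, at 0.00815 FPKM against 0.0808 in the control group. FAM3B, TLL1, HMGCS2 and NR5A2 were not called with siRNA 1 either, at 0.226, 0.209, 0.446 and 0.434 FPKM. Their log2 fold changes with siRNA 1 were 0.98, 0.67, 2.05 and 1.52. Their deposited p-values with siRNA 1 were those of untested rows, so the missing call is no evidence against a change.

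The third question was which changes both siRNAs shared. Of 13141 rows tested in both tables, 1216 rose with both and 987 fell with both, against 459 and 330 for independent lists, while 330 changed in opposite directions, against 789 for independent lists. MGP, an extracellular inhibitor of calcification on chromosome 12 from 14881181 to 14885926, rose from 9.83 to 130 and 82.7 FPKM. The other rises that were highest in both, among single-gene rows that met the level rule, were RP11-369C8.1, UGT2B11, ABCC12, UGT2B10, BRINP3, ATP13A5, HIST1H2BG, the prostaglandin E2 receptor gene PTGER4, LHFP, PLSCR4 and the adenylyl cyclase gene ADCY5, each with a log2 fold change of at least 1.97 with either siRNA. UGT2B genes resemble one another closely, so single members are uncertain. Apart from EPAS1, the lowest shared falls among single-gene rows that met the level rule were those of MUC5AC, ANXA1, S100A2, SERPINE1, LGALS1, GLI1, LRP4, CLGN, HMOX1 and the histone genes HIST1H2BH and HIST2H2AC. LGALS1, which encodes galectin-1 on chromosome 22 from 37675608 to 37679806, fell from 96.8 to 16.1 and 17.7 FPKM. SERPINE1, the plasminogen activator inhibitor on chromosome 7 from 101127089 to 101139266, fell from 7.76 to 1.33 and 1.12 FPKM. GLI1, the Hedgehog pathway transcription factor, fell by 2.96 and by 2.38 on the log2 scale at q-values of 0.0326 and 0.0398 in the authors' deposited tables. The heme oxygenase gene HMOX1 fell from 3.95 to 0.861 and 0.904 FPKM.

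**Figure D1:**
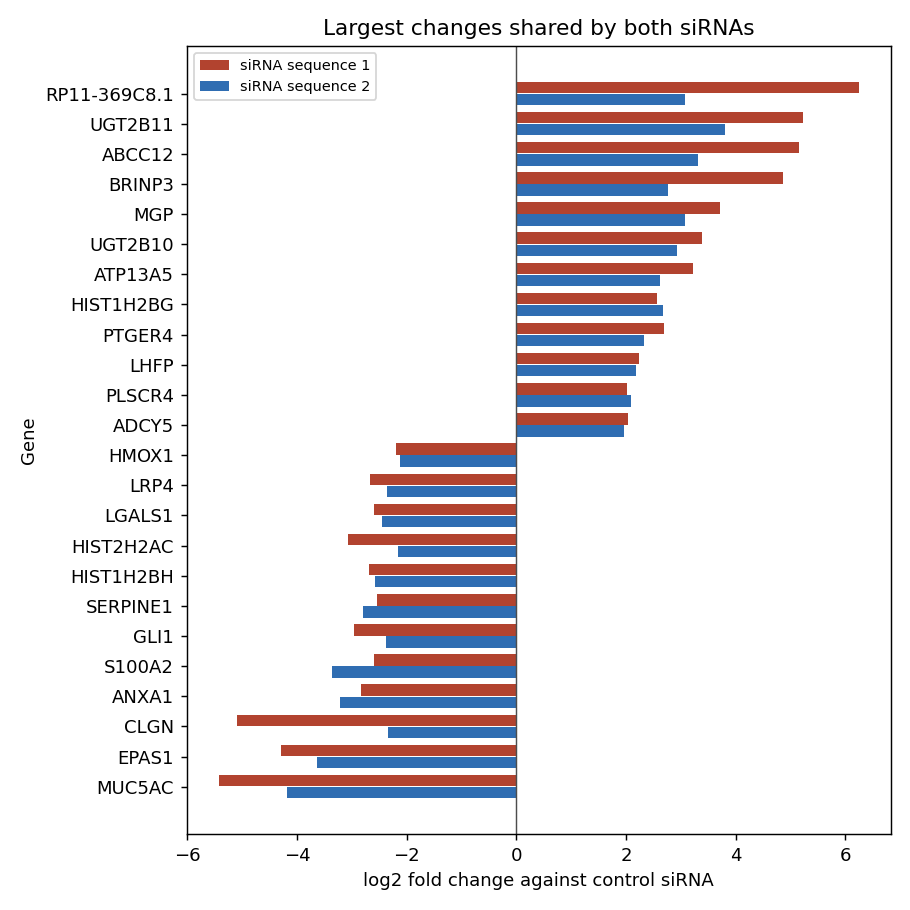
Log2 fold change against the control siRNA (horizontal axis) of the 12 shared rises and 12 shared falls chosen by the fixed rule; red bars are siRNA 1 and blue bars siRNA 2, each a ratio of the authors' pooled FPKM values, so there are no error bars. MGP lies at 3.73 and 3.07, and EPAS1 at -4.30 and -3.63.

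Because both comparisons used the same control samples, agreement between them lies above 0 without any effect. Adjusted calls are close to 0 by construction where no group changes, so simulated unchanged groups against shared controls were compared at an unadjusted p below 0.05 in both and in the same direction. Of 12199 rows with usable standard errors, 2793 met this in the data and 96.2 on average in 100 simulated rounds (78 to 116). The simulated groups hold no change in either arm, so this count does not show that the siRNAs agreed beyond the shared controls. Across 12219 genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r = 0.547 and Spearman's rho = 0.508. Simulated values were 0.434 (0.318 to 0.602) and 0.405 (0.378 to 0.431), so r lay inside its simulated range and rho above it. The simulated fold changes hold error only, with variances of 0.182 and 0.161 for siRNA 1 and siRNA 2, against 0.421 and 0.262 observed. A correlation depends on that spread, so these ranges do not show what shared controls alone would give in the data. The covariance was 0.183 against a simulated 0.0744 (0.0462 to 0.125) with standard errors implied by the authors' p-values, a difference of 0.108. With standard errors taken from the statistic in the authors' deposited tables the simulated covariance was 0.236 (0.146 to 0.397) and the difference -0.0531, so the covariance does not settle the size of a shared effect. Those larger errors alone would give variances of 0.575 and 0.511 for siRNA 1 and siRNA 2, above the observed 0.421 and 0.262. With 1 pooled value per group the controls could not be divided, so part of the agreement may come from the shared controls.

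**Figure D2:**
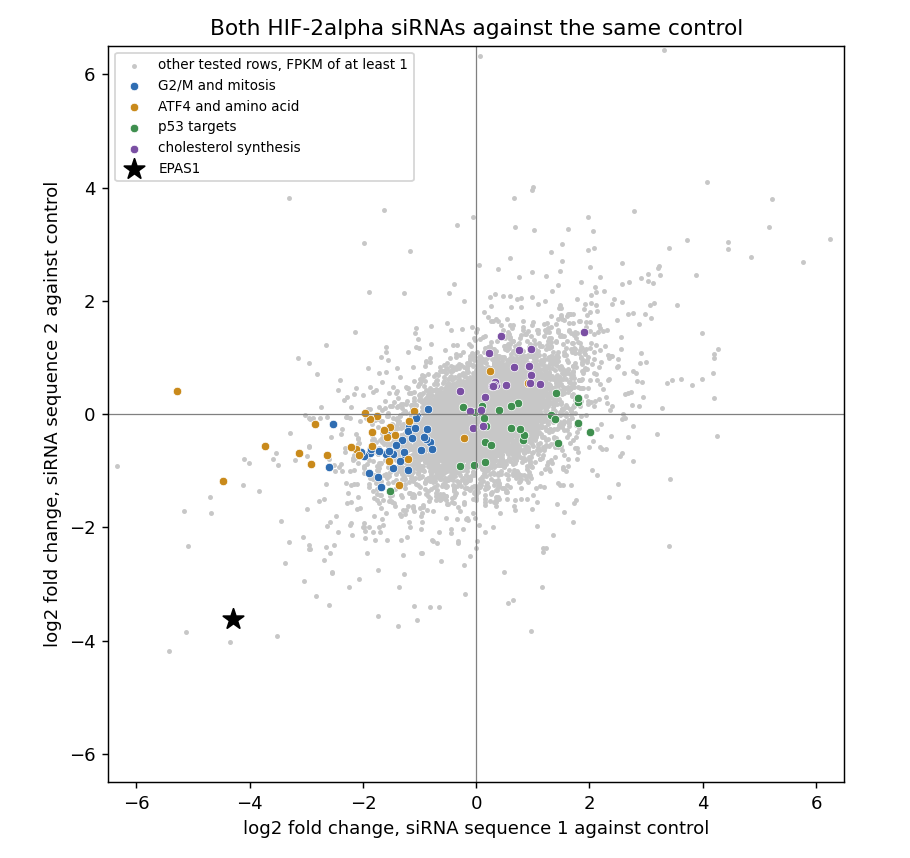
Log2 fold change with siRNA 1 (horizontal axis) and siRNA 2 (vertical axis), both against the same control group. Each grey point is a row tested in at least 1 table with FPKM of at least 1 in a group and above 0 in all; coloured points are tested members of the mitosis (blue), ATF4 (orange), p53 (green) and cholesterol (purple) lists and the star is EPAS1. Of 12751 rows, 3 lie beyond the axes, and r was 0.547 over the 12219 rows that also met the level in both tables.

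All 34 tested members of the G2/M and mitosis list fell with siRNA 1, with a median log2 fold change of -1.32, and 25 fell with siRNA 2, with a median of -0.62. Adjusted over the list alone the counts were 34 and 26. Both medians lay at percentile 0 of 10000 random lists. The proliferation marker MKI67 fell by 1.20 and 0.98 on the log2 scale, the spindle motor CENPE by 1.73 and 1.11, the phosphatase CDC25C by 1.67 and 1.29, and HMMR by 1.89 and 1.05. Of the 31 tested G1/S and replication genes, 13 fell and 5 rose with siRNA 1, and 21 fell and 1 rose with siRNA 2. Their medians were -0.26 (percentile 0.070) and -0.44 (percentile 0), and adjusted over the list alone 20 and 23 changed. E2F2, E2F8, MCM10 and CDC45 were among those that fell with both, MCM10 by 0.59 and 1.23. In this list 12 genes fell with both, and 3 changed in opposite directions. These were CCNE1, PCNA and MCM6, named after their values were seen, which rose with siRNA 1 and fell with siRNA 2.

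**Figure D3:**
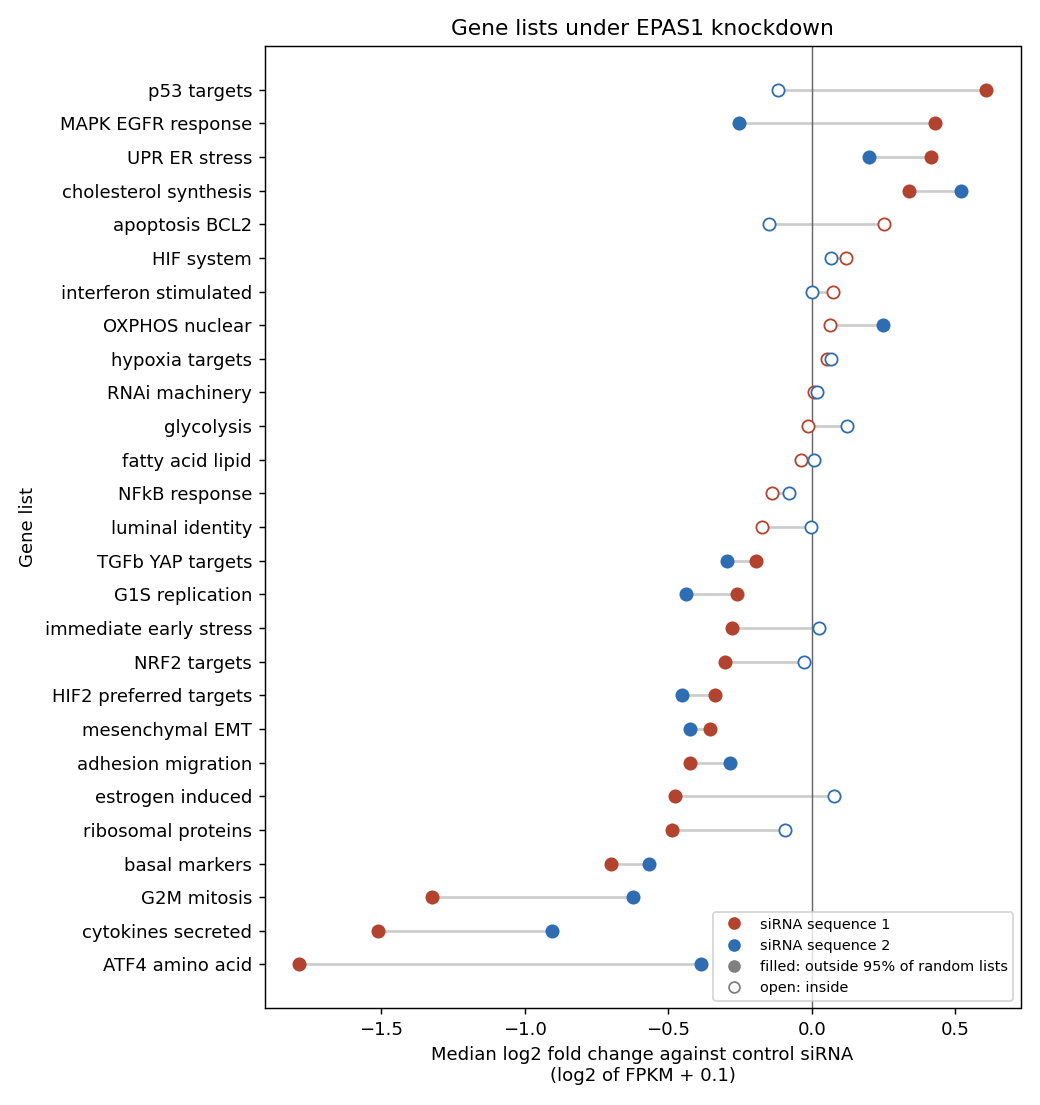
Median log2 fold change of log2(FPKM + 0.1) against the control siRNA for the 27 gene lists with at least 5 expressed members (vertical axis), in red for siRNA 1 and blue for siRNA 2. Filled points lie outside the central 95% of 10000 random lists matched on expression and open points inside, a description of these libraries without error bars; the mitosis list lies at -1.32 and -0.62, and the cholesterol list at 0.34 and 0.52.

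Of 14 tested secreted cytokines, growth factors and proteases, 10 fell and 2 rose with siRNA 1 (median -1.51, percentile 0), and 11 fell and 0 rose of 14 with siRNA 2 (median -0.90, percentile 0.010). The counts adjusted over the list alone were 12 and 11. The EGFR ligand AREG fell from 388 to 131 and 82.8 FPKM, and the urokinase receptor PLAUR from 6.17 to 1.33 and 1.63 FPKM. Basal markers had medians of -0.70 (percentile 0.020) and -0.57 (percentile 0.16), with 6 of 14 and 5 of 13 tested members down, 2 and 0 up, and 8 changed with each siRNA adjusted over the list alone. The laminin subunit LAMC2 and the integrin ITGB4 were among those that fell with both. Over members with FPKM of at least 5 these medians no longer stood apart (-0.37, percentile 3.95, and -0.49, percentile 3.90). Mesenchymal genes had 6 falls and 0 rises among 13 tested genes with each siRNA, with medians of -0.35 (percentile 0.75) and -0.43 (percentile 0.38), and 6 and 7 changes adjusted over the list alone. TNC, COL6A2 and TPM2 fell with both. In the adhesion and migration list 12 of 27 genes fell and 4 rose with siRNA 1, and 13 fell and 1 rose with siRNA 2. The medians were -0.43 (percentile 0) and -0.29 (percentile 0.080), and 17 and 15 genes changed adjusted over the list alone. The hyaluronan receptor CD44 fell from 4.89 to 1.22 and 1.23 FPKM, and the actin-bundling FSCN1 from 6.32 to 2.76 and 3.42 FPKM. TGF-beta and YAP targets fell in 8 and 9 of 20 cases and rose in 5 and 0, with medians of -0.19 (percentile 1.92) and -0.29 (percentile 0.20), and 13 and 9 changes adjusted over the list alone. ID1 and CCN1 were among those that fell with both. SERPINE1 is a member of several of these lists.

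Genes described as regulated mainly by HIF-2 had medians of -0.34 (percentile 1.40) with siRNA 1 and -0.45 (percentile 0.060) with siRNA 2. With siRNA 1, 6 of 13 fell and 3 rose, and with siRNA 2, 5 of 15 fell and 3 rose. Adjusted over the list alone 9 and 10 changed. SERPINE1 and AREG fell with both, and IGFBP3, which binds insulin-like growth factors, fell from 26.0 to 4.81 and 6.16 FPKM, while the iron reductase CYBRD1 rose from 14.8 to 28.6 and 34.8 FPKM. The list did not stand apart with an FPKM minimum of 5 (medians -0.14 and -0.16, percentiles 14.9 and 9.66) or 0.1 (medians -0.14 and -0.16, percentiles 11.6 and 10.7). Of the 29 tested general hypoxia targets, 9 fell and 5 rose with siRNA 1, and 5 fell and 4 rose with siRNA 2. Their medians of 0.05 and 0.07 did not stand apart (percentiles 40.6 and 71.8), and 14 and 9 changed adjusted over the list alone. The angiogenic factor VEGFA fell from 60.7 to 35.8 and 33.7 FPKM and BHLHE40 from 58.5 to 25.6 and 31.7 FPKM, while the mitophagy receptor BNIP3L rose from 61.4 to 100.6 and 89.5 FPKM. Glycolysis genes went both ways, with 5 rises and 5 falls of 18 with siRNA 1 and 3 rises and 5 falls with siRNA 2. The medians were -0.01 (percentile 42.0) and 0.12 (percentile 84.5), and 10 and 9 changed adjusted over the list alone. PGK1, PFKM and PGAM1 rose with both and HK2 fell with both.

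FOXA1, the pioneer transcription factor that opens chromatin for the estrogen receptor, rose from 254 FPKM to 367 with siRNA 1 and 360 with siRNA 2, log2 fold changes of 0.53 and 0.50 with q-values of 0.00117 and 0.000360 in the authors' deposited tables. It lies on chromosome 14 from 37589984 to 37596059 (XLOC_015984). ESR1, which encodes the estrogen receptor, fell from 52.2 to 30.8 FPKM with siRNA 1 and stood at 52.0 FPKM with siRNA 2 (log2 fold change -0.01, q = 0.964 in the authors' deposited table). It lies on chromosome 6 from 151656691 to 152129619. Luminal identity genes did not stand apart, with medians of -0.17 (percentile 7.29) and -0.003 (percentile 38.9). Of 21 tested, 5 rose and 6 fell with siRNA 1 and 6 rose and 5 fell with siRNA 2, and adjusted over the list alone 12 and 14 changed. TFAP2C, EPCAM and TOB1 rose with both. Estrogen-induced genes had a median of -0.48 with siRNA 1 (percentile 0; 11 of 25 fell and 3 rose) and 0.08 with siRNA 2 (percentile 74.7; 4 fell and 6 rose). With q adjusted over the list alone, 14 and 10 changed. STC2 fell from 119 to 15.8 and 64.5 FPKM, while GREB1 and the receptor tyrosine kinase gene RET rose with both, RET from 26.6 to 56.0 and 56.4 FPKM.

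Metabolic groups moved in both directions. Targets of the stress transcription factor ATF4 and genes of amino acid supply fell in 25 of 28 cases and rose in 1 with siRNA 1, with a median of -1.79 (percentile 0). With siRNA 2, 15 fell and 3 rose, with a median of -0.39 (percentile 0). With q adjusted over the list alone, 26 and 21 changed. NUPR1 went from 202 to 9.12 and 88.6 FPKM, CBS from 15.9 to 6.19 and 6.67, and CEBPB from 72.1 to 31.3 and 41.4, whereas CHAC1 rose with siRNA 2 to 40.2 FPKM. Cholesterol synthesis genes rose in 14 of 22 cases with siRNA 1 and 18 of 22 with siRNA 2, and 1 fell with each. The medians were 0.34 (percentile 99.3, or 97.3 among unmatched random lists, which no longer stands apart) and 0.52 (percentile 100), and 17 and 19 changed adjusted over the list alone. DHCR24, which catalyses a late step of the pathway, rose from 105 to 395 and 288 FPKM, and IDI1, SC5D and SQLE rose with both. Fatty acid and lipid genes did not stand apart (medians -0.04 and 0.01, percentiles 23.4 and 46.3). Of 21, 5 rose and 6 fell, then 3 rose and 3 fell, and 11 and 6 changed adjusted over the list alone. SCD and FASN rose with both, FASN from 221 to 418 and 343 FPKM.

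The p53 target list had 14 rises and 2 falls among 26 genes with siRNA 1, with a median of 0.61 (percentile 100), and 1 rise and 9 falls with siRNA 2, with a median of -0.12 (percentile 6.77). Over members with FPKM of at least 0.1 the siRNA 2 median stood apart (-0.18, percentile 1.26). Changes adjusted over the list alone numbered 18 and 11. SESN1 rose with both and GDF15 fell with both. CDKN1A, the cell cycle inhibitor p21, named after its values were seen, rose with siRNA 1 by a log2 fold change of 1.80 and had -0.15 with siRNA 2. Cytosolic ribosomal protein genes fell in 43 of 51 cases with siRNA 1 (median -0.49, percentile 0) and in 8 with siRNA 2 (median -0.09, percentile 2.64, or 2.44 with a pseudocount of 1, which stands apart). None rose, and 45 and 5 changed adjusted over the list alone. RPL23 and RPL12 fell with both over all genes tested, but neither passed with siRNA 2 when adjusted over the list alone (p = 0.0143 and p = 0.0061 in the authors' deposited table). Pseudogene copies make single members uncertain. Of 17 MAPK response genes, 10 rose and 5 fell with siRNA 1 (median 0.43, percentile 99.1), and 2 rose and 8 fell with siRNA 2 (median -0.25, percentile 1.36). Changes adjusted over the list alone numbered 15 and 10. The MYC oncogene fell from 73.8 to 32.6 and 38.9 FPKM and SPRY4, a feedback inhibitor, rose from 34.4 to 95.6 and 59.9 FPKM.

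In all, 17 of 27 lists stood apart with siRNA 1 and 13 of 27 with siRNA 2, where 1.35 would among lists of randomly drawn genes. Genes of a list can move together and some lists share members, so 1.35 is not a chance expectation for these lists. Few markers of other cell types were tested, too few to be summed up. The fibroblast marker COL1A1 stood at 30.8, 31.8 and 32.8 FPKM in the control, siRNA 1 and siRNA 2 groups and did not pass the threshold, and none of 3 tested endothelial markers did, of which EMCN stood at 2.97, 3.45 and 3.73 FPKM. COL3A1, the other fibroblast marker tested with siRNA 1, named after its values were seen, rose from 0.359 to 1.49 FPKM with siRNA 1, in a row merged with a non-coding gene. The leukocyte marker ITGB2 fell from 3.19 to 1.60 FPKM with siRNA 2 and was at 4.77 FPKM with siRNA 1, where it did not pass the threshold. These 3 lists had under 5 expressed members, so no percentile was computed, and their counts were the same adjusted over the list alone. Of 13 mitochondrially encoded genes, 2 were matched to a row, both listed at 0, so RNA quality could not be read from them. Immediate-early and heat shock genes, a sign of handling, had a median of -0.28 with siRNA 1 (percentile 0.93; 5 of 20 rose and 7 fell) and 0.03 with siRNA 2 (percentile 51.7; 2 of 18 rose and 8 fell), and 14 and 11 changed adjusted over the list alone. The small heat shock protein gene HSPB1 fell from 1968 to 779 and 730.2 FPKM, while the chaperone gene HSP90AA1 rose from 466 to 800.5 and 624 FPKM.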

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

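The comparison of siRNA 1 with siRNA 2 was chosen after the data were seen, as were the tests of scaling and knockdown depth, the count of members without the seed core, and the ESR1 test; the test of a seed match in list members was written before its result was seen. A difference between groups was read from the median log2 ratio of the 2 siRNA groups over each list, placed among 10000 matched random lists. Of 27 lists 8 stood apart, where 1.35 would among lists of randomly drawn genes, which do not move together as genes of a list can. The comparison is of pooled levels, without a test over replicates. The ATF4 list lay at -1.34 and the estrogen-induced list at -0.43. Among the others, the G2/M and mitosis list lay at -0.84 and ribosomal proteins at -0.38. On the higher side with siRNA 1 were the p53 targets at 0.86, the MAPK response at 0.65, G1/S replication at 0.26 and the unfolded protein response at 0.22 (91.8 as percentile among unmatched random lists, which no longer stands apart).

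ATF4 targets were lower with siRNA 1 than with siRNA 2, and ATF4 mRNA itself, named after its value was seen, fell by 1.10 on the log2 scale with siRNA 1 and stood at 0.06 with siRNA 2. Scaling between the libraries is argued against, since the difference of list medians was -1.40 as deposited and -1.48 after each arm had been centred on its median gene. Direct repression through the leading 3' UTR word of siRNA 1 is argued against too, for the 23 of 27 searched members that lack it. Their median difference was -1.35, the same as over all 27. Other seed matches of that siRNA, such as an overlapping word or a shorter core, were not counted in this list. Direct repression through those matches stays open. A deeper EPAS1 knockdown with siRNA 1 stays open: the siRNA 1 median of -1.79 lay at percentile 0 of random lists matched on the siRNA 2 fold change, but the list was taken up because the siRNAs differed in it, so that value decides nothing. An effect of siRNA 1 outside EPAS1 that acts upstream of ATF4 may also account for the difference and was not tested.

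Estrogen-induced genes were lower with siRNA 1 than with siRNA 2, with TFF1, named after its values were seen, at 5770 FPKM in the control group, 1440 with siRNA 1 and 7255 with siRNA 2; over members with FPKM of at least 5 the list lay at -0.18, percentile 5.07, and no longer stood apart. Scaling is argued against by a centred difference of medians of -0.63 (-0.55 as deposited), while a deeper EPAS1 knockdown stays open, since percentile 0 among random lists matched on siRNA 2 restates the difference for which the list was taken up. The planned test of direct repression through a seed match went the way that explanation needs, with a median difference of -0.17 over the 18 searched members without the word against -0.46 over all 21. A seed match in each member that fell is argued against, since 7 of the 11 searched members that fell lack even its 6-base core. Lower ESR1 mRNA with siRNA 1, a log2 difference of -0.75 between the siRNAs, remains a candidate explanation. The 3' UTR of ESR1 carries the word once, and 10.2% of searched genes of all UTR lengths carry it at least once. The searched ESR1 3' UTR is 4311 bases long, and a longer UTR is likelier to hold any given word. The match is therefore weak evidence.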

How the results depend on the processing

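No paired analysis was possible because the tables hold 1 pooled value per group and no value per sample. For the same reason leaving out each replicate and other splits of the samples could not be run.
The settings named here were planned, except the comparison of the siRNAs with each other, the rescaling of single genes, the counts by 3' UTR word and the errors behind the simulated covariance, which were chosen after the data were seen. EPAS1 knockdown kept its direction under centring and pseudocounts. With a minimum change of 0.58 on the log2 scale, counts fell to 3133 with siRNA 1, 1840 with siRNA 2 and 871 shared, by construction, and the share of rises with siRNA 2 went from 50.4% to 43.1%. Across q thresholds of 0.01 and 0.1 the counts were 3962 to 6088 for siRNA 1, 2942 to 4870 for siRNA 2 and 1508 to 2699 shared. The correlation between siRNAs was 0.533 with an FPKM minimum of 0.1, against 0.547, and the cause was not tested. The covariance between the siRNAs exceeded the simulated one by 0.108 with errors implied by the p-values and lay at -0.0531 from it with errors from the deposited statistic, which are larger by construction. The number of list medians that stood apart, 30 over both siRNAs, ranged from 25 to 31. Counting the comparison between the siRNAs too, 6 medians ceased to stand apart at an FPKM minimum of 5; at 0.1, 2 ceased and 3 began to; with unmatched random lists 3 ceased and 2 began to; with a pseudocount of 1, 2 began to. No list median that stood apart and no called named gene reversed its sign. Centring moved the siRNA 1 values by 0.09 and the siRNA 2 values by 0.01. Among 1951 shared changes with 1 row per symbol, 1082 were rises. Depth per sample was not in the tables, so no limit from depth can be given.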

Other observations

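The tests of single siRNA seed words were chosen after the scan had been seen, and the test of the control siRNA was written before its result.

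Unfolded protein response genes rose in 11 of 23 cases with siRNA 1 and 10 of 23 with siRNA 2, and 4 and 3 fell, with medians of 0.42 (percentile 99.9) and 0.20 (percentile 97.98, or 97.0 among unmatched random lists, which no longer stands apart). Adjusted over the list alone 17 and 14 changed. The disulfide isomerase PDIA3 rose from 267 to 437 and 374 FPKM, EDEM1 and DERL1 rose with both, and the sensor ATF6 fell with both, from 17.2 to 10.3 and 12.5 FPKM. Nuclear-encoded oxidative phosphorylation genes had a median of 0.06 with siRNA 1 (percentile 75.5; 8 of 32 rose and 4 fell) and 0.25 with siRNA 2 (percentile 99.8; 14 rose and 1 fell). Adjusted over the list alone 12 and 18 changed, and ATP5F1A rose from 328 to 532 and 474 FPKM. NRF2 targets had a median of -0.30 with siRNA 1 (percentile 1.42; 2 of 18 rose and 7 fell) and -0.03 with siRNA 2 (percentile 31.7; 5 rose and 2 fell), with 12 and 7 changed adjusted over the list alone. With siRNA 1 the list did not stand apart over members with FPKM of at least 5 (percentile 8.72). Its members went apart with both siRNAs: the quinone reductase NQO1 rose from 1197 to 1724 and 2090 FPKM while HMOX1 and the ferritin heavy chain FTH1 fell, FTH1 from 3666 to 2156 and 1825 FPKM.

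The remaining lists did not stand apart with either siRNA. Apoptosis genes of the BCL-2 family had medians of 0.25 (percentile 90.2; 6 of 20 rose and 3 fell) and -0.15 (percentile 5.21; 2 rose and 7 fell), with 11 and 9 changed adjusted over the list alone. BIK rose and PMAIP1 fell with both. Interferon-stimulated genes had medians of 0.07 (percentile 38.7; 3 of 15 rose and 5 fell) and 0.00 (percentile 51.7; 2 of 14 rose and 2 fell), with 10 and 4 changed adjusted over the list alone, and ISG15 fell with both. NF-kB targets had medians of -0.14 (percentile 10.9; 3 of 11 rose and 4 fell) and -0.08 (percentile 29.4; 1 of 12 rose and 2 fell), with 9 and 3 changed adjusted over the list alone. CXCL8 fell from 20.1 to 2.05 and 15.9 FPKM and CD83 rose with both. In the small RNA pathway 2 of 13 genes rose with siRNA 1 and 3 with siRNA 2, none fell, and the medians were 0.01 (percentile 29.8) and 0.02 (percentile 54.7), with 2 and 3 changed adjusted over the list alone.

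Each siRNA went with lower expression of genes whose 3' UTR carries a particular 7-base word, in the pattern that partial pairing of an siRNA seed to other transcripts is known to give. With siRNA 1 the most negative of 15486 words was AAGACTA, at z = -6.87 against a permuted bound of -4.88, followed by the overlapping AGACTAA; with siRNA 2 it was TCACCAA at z = -8.02 (bound -5.09), followed by the overlapping TTCACCA, and the leading words had z of 0.18 and 2.05 in the other arm. AAGACTA, TCACCAA and TTCACCA occur in the EPAS1 transcript, and AGACTAA does not. As 3957 of the 15486 searched words occur there, presence in EPAS1 is weak evidence. Seed-matched repression by each siRNA is a candidate explanation, and it could be checked against the siRNA sequences, which were not used here. The effect was small, with median log2 fold changes of -0.06 with AAGACTA and 0.09 without. With siRNA 1, 27.0% against 17.6% of genes fell (24.95% against 16.7% for TCACCAA with siRNA 2). Without genes that carry either word, 1402 of 7348 searched genes changed the same way with both siRNAs, against 1736 of 9091. Neither word went with lower expression in the other arm, so this shared count could hardly move. It does not measure how much seed matches contributed, and genes with only an overlapping word or shorter core stayed in it. A seed of the control siRNA was not detected, since no word passed the bound for the mean of both arms (highest z = 4.03, bound 5.09). The leading word was 1.24 times as frequent among 948 shared rises (25.8%) as among other genes (20.9%). Most shared rises lack that word, so it is not a direct source of most of them. The words of siRNA 1 and siRNA 2 had small effects too, so a control seed behind some of the rises is not excluded.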
